A study of Danio rerio with 18 samples.

How the data were processed

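The series holds 18 Affymetrix arrays of zebrafish (Danio rerio) brain RNA, 1 array per sample, in 6 groups of 3. Tissue of the nucleus of the medial longitudinal fascicle (NMLF) was taken by laser capture from fish with a transected spinal cord and from sham-operated fish, 4 h, 12 h and 11 d after surgery. Groups and replicate numbers came from the sample titles. The labels do not say which animal each sample came from or whether tissue was pooled, so the p-values measure the spread between these samples only, and they are too small if samples of a group share an animal.

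Per the labels, RNA was purified with a micro-scale column kit, amplified, and prepared as biotin-marked cDNA by the standard Affymetrix procedure. The deposited values are 1 probe-set intensity per array on a linear scale, as the values themselves show, and the program that combined probes into probe sets is not given in the sources used here. The mean signal after trimming 2% at each end was 150.0 on 16 arrays, and 100.4 and 92.6 on the sham and the transected array of replicate 3 at 4 h, so the deposited arrays were not all on one scale. Per array, 22.8% to 39.8% of probe sets lay below a signal of 16.

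The analysis plan assumed log2 values and named a fallback for linear ones, which was used: quantile normalization across the 18 arrays, a floor at a signal of 16, then log2. After this step 27.5% to 27.6% of probe sets lay at the floor on each array, 2009 probe sets on all 18 arrays and 6573 on at least 1. Probe sets at the floor on all arrays cannot reach a small p, so the count that chance gives at an unadjusted p under 0.05 is taken over the other 13493 (674.65). Over all 15502 it would be 775.1. The 115 control probe sets were left out of the tests, which left 15502 of 15617. GEO's annotation of the platform gave a single gene symbol for 10795 of the tested probe sets, several for 135 and none for 4572, and a probe set with several or none is named only by its identifier. The 10795 stand for 8793 genes, of which 8723 were found by gene number in a RefSeq table. No genome build is named in the sources used here, so no coordinates are given. All signals below are normalized, floored values, group levels are geometric means, SEs come from the model without pairs unless called paired, and the number of arrays limits their precision.

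A linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 12 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the 15502 probe sets with a threshold of 0.05. The contrasts were transected minus sham at each time, their average, a moderated F test that the 3 injury effects are equal, and a moderated F test over the 3 sham groups. Probe sets at the floor have almost no variance, and the prior had only 0.51 degrees of freedom. With the dimmest probe sets left out, which kept the brightest 10334, it had 5.80, so counts from that setting stand beside the main ones.

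Gene lists, 29 in all, were tested with camera (preset correlation 0.01, at least 5 measured genes, adjusted over the lists within a contrast) on the brightest probe set of each gene. Camera asks whether a list moved more than other genes. An estimated correlation was run as well, and so was fry, which asks whether a list's genes move on balance one way. Lists built from name patterns caught a few genes outside their theme: rps6ka1 and rps19bp1 among ribosomal proteins, psmc3ip and psme3ip1 among proteasome subunits, rtn4ip1, unc50, cflara, cttnbp2, tubgcp2 and tubgcp3 elsewhere, assembly factors such as ndufaf1 among oxidative phosphorylation genes, and hbp1, an HMG-box gene, among erythrocyte markers. The cholesterol synthesis list also holds fads2 and scd, fatty acid desaturases, and stard4, a sterol carrier. The list of candidates from follow-up studies was drawn from work on this same preparation. Some lists share genes, so their calls are not independent. Examples are tmsb and tubb5 (axon regeneration and cytoskeleton), mmp9 (inflammation and matrix), and lgmn and mvp (candidates and lysosome).

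Contrasts, lists, main settings, the rule for naming genes and most alternatives were fixed before the data were examined. Under the rule, up to 12 rises and 12 falls past the threshold without overlap between groups were picked for naming. Where fewer than 10 genes passed, the 6 rises and 6 falls with the smallest unadjusted p among probe sets brighter than the median followed, given as not passing. The 4 members of each called list that moved furthest in its direction were picked too, as were the candidate genes, gap43, atf3 and jun. Not all genes picked by the rule are given below, and which of them are given was not fixed beforehand. Called probe sets without a single symbol, genes passing only with the dimmest probe sets left out, and list members passing over their list alone were named after their values were seen.

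Groups share replicate numbers, so pairing was checked before calls were compared, from the correlation of deviations from the group means over all probe sets. Same-numbered sham and transected arrays gave 0.62, 0.38 and 0.26 at 4 h and 0.23, 0.48 and 0.64 at 11 d, all above 0.1, so by a rule set beforehand the numbers were taken to pair arrays at these times. Differently numbered arrays reached 0.23 (sham 2 with transected 3) and 0.11 (sham 3 with transected 2) at 4 h. At 11 d they reached 0.34 (sham 2 with transected 1) and 0.22 (sham 1 with transected 2). Other matchings thus meet the rule at both times, so it cannot show that the numbers pair arrays. The pairs, paired SEs and replicate block below all rest on it. The pairing of replicates 2 and 3 at 4 h and of replicates 1 and 2 at 11 d is therefore weak. At 11 d replicate 3 stands apart in both groups. At 12 h same-numbered arrays gave 0.11, -0.01 and 0.14, so there the arrays share only a number. No labels say what a number stands for.

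The model was tested on simulated data with means over all arrays and a spread pooled over all groups, not those of 11 d alone. Probe sets were drawn independently and without pairs. Changes were placed in the comparison at 11 d, among the brightest 10334 only. Over 15502 probe sets, the model recovered 28.7% of genes changed by 2-fold and 69.7% of those changed by 4-fold in 3 runs. There were 28 false calls. Over 10334 these values were 31.3%, 77.3% and 16. Recovery at the spread of the 11 d arrays themselves was not tested. Camera found a list of 40 genes shifted by 0.5 among 8793 genes in 5 of 5 runs and called 0 of 140 other lists. These genes too were drawn independently, so the runs do not show how often camera calls lists falsely when genes move together. Alternatives covered median centring, the deposited scale, array weights, an intensity trend, other floors and thresholds, 1 probe set per gene, the replicate block, the arrays of a single time, the GAPDH ratio as a covariate, and each array left out in turn.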

Results

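Gene expression was measured in the NMLF, a midbrain group of neurons whose axons run down the spinal cord and, in zebrafish, grow back after the cord is severed. Transected and sham-operated fish were compared at 4 h and 12 h, early after surgery, and at 11 d, in the period of axon regrowth. Each of the 6 groups had 3 arrays. Arrays of a group correlated at 0.936 to 0.984 over probe sets, and no array pair held identical values. The ratio of the 3' to the 5' GAPDH control probe sets, which grows as RNA is degraded or shortened, was compared between groups. Its geometric means were 1.65 (sham) and 1.89 (transected) at 4 h, 3.99 and 4.61 at 12 h, and 2.02 and 2.24 at 11 d. In exact permutation tests, sham and transected arrays differed at p = 0.2, 0.4 and 0.7 at the 3 times, where 3 against 3 arrays cannot go below 0.1. The lowest ratio among the 6 arrays at 12 h was 3.15, above the highest of the other 12 arrays, 2.88. The first principal component held 31.3% of the variance. The replicate 3 arrays at 11 d scored 17.4 (sham) and 23.8 (transected), while the other 4 arrays of that time scored from -36.5 to -23.9. At 4 h sham replicates 1 to 3 scored -17.3, 40.2 and 10.1 and transected replicates -24.8, 15.4 and 11.1, so sham replicate 2 had the highest score of the 6.

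**Figure D1:**
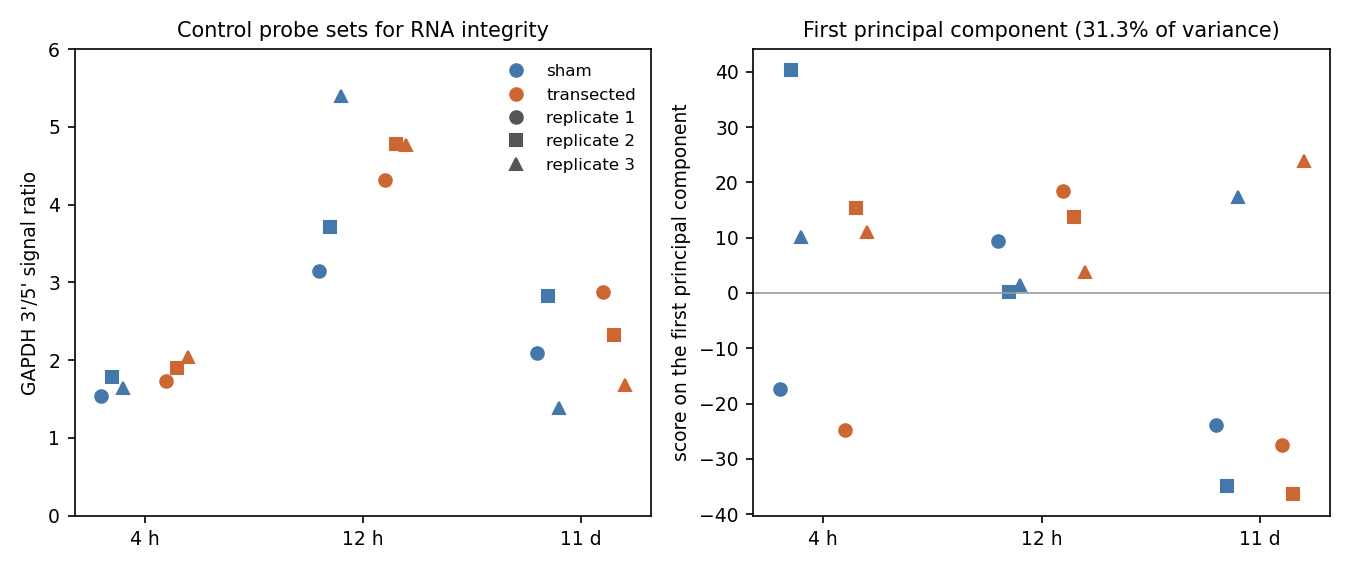
GAPDH 3'/5' signal ratio of each array (left) and its score on the first principal component (right), by time after surgery; color gives sham or transected and marker shape the replicate. All 6 arrays at 12 h have ratios of 3.15 or more, and the replicate 3 arrays at 11 d (17.4 and 23.8) lie apart from replicates 1 and 2 of their groups.

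At 4 h, 12 of 13 measured genes of cholesterol synthesis were higher after transection than after sham surgery (3 arrays each), with a median log2 change of 0.29. Replicates 1 and 2 carried this: within same-numbered arrays the list medians were 0.65, 0.82 and -0.03. Among its genes hmgcs1, an early enzyme of the pathway, went from a signal of 897 to 1536 (log2 change 0.78 ± 0.33, SE; higher in 2 of 3 pairs, paired SE 0.44) and mvk, mevalonate kinase, from 33.1 to 63.3 (0.94 ± 0.36, 3 of 3 pairs). Of 18 glucocorticoid-responsive genes 13 were higher, with a median of 0.40. The largest changes were those of cebpd, a transcription factor of the acute stress response, at 1.22 ± 0.48 (621 to 1447), and pfkfb4b, a regulator of glycolysis, at 1.09 ± 0.41. Neuron markers had a median of -0.14 with 23 of 31 genes lower, but 0.0079 without transected replicate 1. Lower members were the sodium pump subunits atp1a3a (-0.57 ± 0.47) and atp1b2a (-0.47 ± 0.28) and the GABA-synthesis gene gad1b (-0.37 ± 0.16). No single gene passed: limma called 0 of 15502 probe sets, and 0 with the dimmest probe sets left out. Of the 13493 probe sets that vary, 352 were at an unadjusted p under 0.05, where chance gives 674.65.

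By camera, 8 of 29 lists passed at 4 h, 5 higher and 3 lower, and none passed with an estimated correlation. Single arrays carried many of these calls: 2 lists passed without sham replicate 3, both higher, and 3 without transected replicate 1. Cholesterol synthesis and glucocorticoid-responsive genes had camera adjusted p-values of 0.0023 each (adjusted p = 0.47 and 0.46 with an estimated correlation), and neuron markers had 0.0099 (adjusted p = 0.54 with an estimated correlation). Axon guidance ligands and receptors were lower in 33 of 43 genes, with a median of -0.17 (camera adjusted p = 0.0023, and adjusted p = 0.54 with an estimated correlation). The Slit receptor robo2 was at -0.75 ± 0.75 and the netrin ntn1a at -0.64 ± 0.64. Neurotransmitter receptors and ion channels were lower in 35 of 54, with a median of -0.13 (0.021, and adjusted p = 0.60 with an estimated correlation). The glycine receptor subunit glra1 was at -0.81 ± 0.79. The channel median was 0.00 without sham replicate 2 (0.76) or transected replicate 1 (0.78), and that of axon guidance -0.030 without transected replicate 1 (0.52). Without sham replicate 2 axon guidance was at -0.09 (0.049) and neuron markers at -0.08 (0.0078). These gene errors are unpaired. Within same-numbered arrays robo2, ntn1a, glra1, atp1a3a, atp1b2a and gad1b were lower in 3 of 3 pairs, with paired SEs of 0.17, 0.32, 0.30, 0.26, 0.10 and 0.18, and none passed with the replicate block (limma adjusted p = 0.43 to 0.90). Cytosolic ribosomal proteins were higher in 60 of 74 with a median of 0.11 (0.0016, and adjusted p = 0.60 with an estimated correlation). Their median was 0.24, -0.01 and 0.07 within pairs 1 to 3, and -0.016 on the deposited scale without further normalization. Inflammation and complement genes were higher in 30 of 39 with a median of 0.20 (0.021, and adjusted p = 0.47 with an estimated correlation), and socs3b, an inhibitor of cytokine signalling, was at 0.64 ± 0.47. The list median was 0.04, 0.09 and 0.10 within pairs 1 to 3. It was as low as 0.033 over 13 other settings, of which 6 lost the call. Apoptosis and p53 genes were higher in 21 of 31 with a median of 0.10 (0.021, adjusted p = 0.37 with an estimated correlation, 0.061 with the replicate block and 0.064 with the dimmest probe sets left out), with the survival gene mcl1b at 0.74 ± 0.34. With the replicate block oxidative phosphorylation passed instead, at 0.041 (adjusted p = 0.83 with an estimated correlation), against 0.12 without it. Over the list alone flna, hk2 and cdt1 passed within the cytoskeleton, glycolysis and cell cycle lists, which did not pass themselves. The smallest unadjusted p-values belonged to g3bp1, a stress granule protein, at 0.51 ± 0.10 (adjusted p = 0.60), and flna, an actin crosslinker, at 0.51 ± 0.11. Downward, the transcription factor gata3 was at -0.49 ± 0.12. None of the 8 candidates from follow-up studies passed. The injury genes atf3, gap43 and jun were at 0.81 ± 0.50, 0.08 ± 0.28 and 0.65 ± 0.37. Their paired SEs were 0.07, 0.08 and 0.25, with atf3 and jun higher in 3 of 3 pairs and gap43 in 2 of 3. With the replicate block limma called 0 probe sets at 4 h.

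At 12 h, limma called 4 probe sets higher and 0 lower, all with sham arrays at or next to the floor signal of 16. They were cdk5rap2, a centrosome gene, at least 2.78-fold higher in transected fish (signal 44.5, log2 change 1.48 ± 0.07, adjusted p = 1.2e-06), and cbsb, a cystathionine beta-synthase gene, at least 1.74-fold higher (27.8, 0.80 ± 0.07, adjusted p = 6.0e-04). A pair without a gene name followed, Dr.23106.1.A1_at (0.24) and Dr.17247.1.A1_at (0.20). Among brighter genes that did not pass, riok1, a kinase of ribosome maturation, was at 1.14 ± 0.19 (adjusted p = 0.12), and irak4, a kinase of Toll-like receptor signalling, at 0.74 ± 0.14. The p53-binding tp53bp2a was at 1.34 ± 0.31 and psme3ip1 at 1.21 ± 0.24. Downward, the glutathione peroxidase gpx1a was at -1.30 ± 0.29 (687 to 279, adjusted p = 0.40) and the DNA polymerase poll at -0.91 ± 0.20. With the dimmest probe sets left out, which removes all 4 called probe sets, limma called 0. Of the 13493 probe sets that vary, 715 were at an unadjusted p under 0.05, where chance gives 674.65.

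Of the lists at 12 h, 3 passed by camera and none with an estimated correlation. Oxidative phosphorylation genes were lower in 66 of 90, with a median of -0.10 (adjusted p = 0.013, and adjusted p = 0.999 with an estimated correlation), with cox4i1l at -0.62 ± 0.34 and sdhdb at -0.53 ± 0.35. Cytosolic ribosomal proteins were higher in 49 of 74, with a median of 0.09 (0.044, and adjusted p = 0.999 with an estimated correlation). Cell cycle genes were higher in 31 of 50, with a median of 0.04 (0.038, and adjusted p = 0.64 with an estimated correlation), and kif23, a kinesin of cytokinesis, at 0.99 ± 0.18 (16.2 to 32.3) passed over the list alone. Oxidative phosphorylation and cell cycle genes no longer passed with the dimmest probe sets left out (0.095 and 0.57), while inflammation and complement genes and erythrocyte markers did (0.012 and 0.0061), at adjusted p = 0.78 and 0.46 with an estimated correlation. Over their lists alone c4b, col5a2a and psme3ip1 also passed. The candidates were between -0.14 and 0.56. For comparison, gap43, atf3 and jun were at 0.12 ± 0.28, 0.89 ± 0.50 and 0.48 ± 0.37. The 12 h arrays carried the higher GAPDH ratios given above, and without transected replicate 3 the 12 h count was 27 probe sets and 0 lists.

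At 11 d, in the period of regrowth, limma called 7 probe sets, 5 higher and 2 lower. The complement gene c4b (Dr.12491.1.A1_at) rose from 20.2 to 145 (log2 change 2.85 ± 0.37, SE, 3 arrays per group, adjusted p = 0.012). So did tnfaip6, a hyaluronan-binding protein of inflamed tissue, from 18.4 to 59.9 (1.71 ± 0.16, adjusted p = 5.2e-04), and jag1a, a Notch ligand, by at least 1.74-fold from sham arrays wholly at the floor (0.80 ± 0.08, adjusted p = 7.1e-04). The aromatase cyp19a1b, which makes estrogen in radial glia of the fish brain, fell from 394.5 to 31.6 (log2 change -3.64 ± 0.47, adjusted p = 0.012). The first enzyme of heme synthesis in red cells, alas2, fell from 222 to 45.3 (-2.29 ± 0.34, adjusted p = 0.033). Its sham level was 93.3 at 4 h and 79.5 at 12 h, and its transected level 79.4 and 56.5, so the 11 d sham arrays stood high for alas2. A pair of unnamed probe sets, Dr.6709.1.S1_at and Dr.23443.1.A1_at, rose from 27.0 to 403 (3.90 ± 0.32) and from 25.3 to 274 (3.44 ± 0.19). Of the 13493 probe sets that vary, 685 were at an unadjusted p under 0.05, where chance gives 674.65. With the replicate block, the 5 named genes had adjusted p-values of 0.16, 0.065, 0.057, 0.24 and 0.24, in the order above. The block's 6 calls shared only the unnamed pair with the 7.

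With the dimmest probe sets left out, 15 probe sets passed at 11 d, 13 higher and 2 lower, and 5 were shared with the main count: c4b (adjusted p = 6.3e-04), cyp19a1b (3.9e-04), alas2 (0.0034) and the unnamed pair. The further rises were mmp9, a matrix-degrading protease, from 48.4 to 509 (3.40 ± 0.58, adjusted p = 0.0059), socs3b from 133 to 740 (2.47 ± 0.47, 0.015), the terminal complement gene c6.2 from 24.0 to 120.1 (2.32 ± 0.40, 0.0081) and the surface glycoprotein thy1 from 114 to 574 (2.33 ± 0.42, 0.012). Others were angptl4, from 30.2 to 160.5 (2.41 ± 0.39, 0.0059), the metalloreductase steap4 from 32.8 to 133 (2.02 ± 0.42, 0.044). The EGF receptor ligand hbegfa rose from 40.3 to 142 (1.82 ± 0.30, 0.011) and the actin-binding thymosin tmsb from 2302 to 5832 (1.34 ± 0.23, 0.039). For c6.2 the sham level was 63.9 at 4 h and 64.2 at 12 h, so its 11 d sham arrays stood low. Adding the replicate block, a combination chosen after seeing the data, gave 43 calls, 36 higher and 7 lower, which held all 15. It added wnt4b (3.40 ± 0.79, 66.0 to 698, adjusted p = 0.0057), stat3, the transducer of cytokine signals, at 1.55 ± 0.56 (0.0053). Also added were the interferon-induced isg15 at 1.80 ± 0.46 (0.012), the ferritin gene fthl30 at 2.74 ± 0.61 (paired SE 1.12, 0.042) and, downward, msmo1, a sterol oxidase, at -1.40 ± 0.40 (0.019). Opposite to isg15, ifi44f1, also of an interferon-induced family, was at -1.37 and lower in 3 of 3 pairs. Leaving out both replicate 3 arrays at 11 d, which stood apart on the first component, gave 26 calls in the full table and 15 with the dimmest probe sets out.

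**Figure D2:**
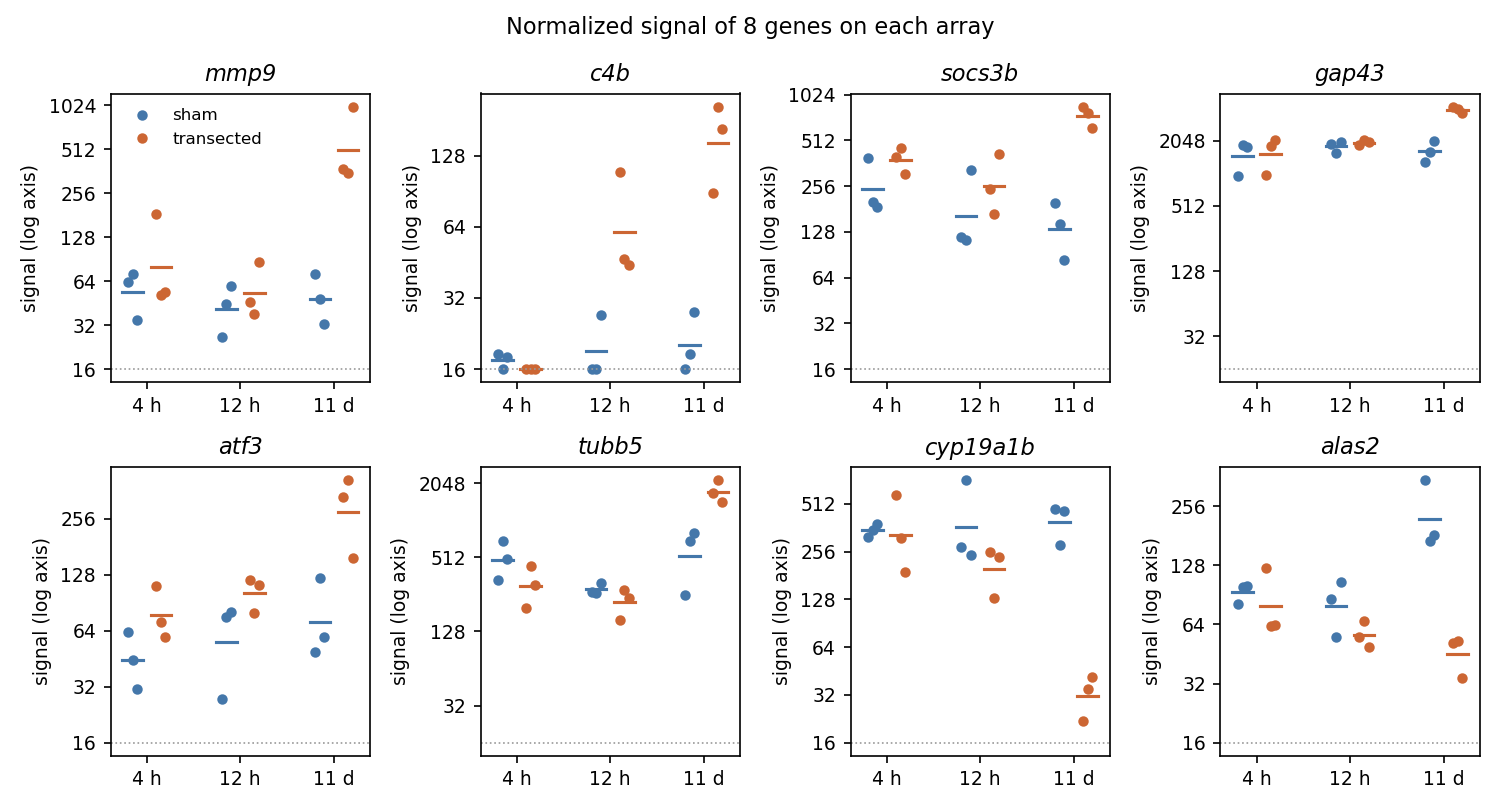
Normalized signal (log axis) of mmp9, c4b, socs3b, gap43, atf3, tubb5, cyp19a1b and alas2 on each array, by time and surgery; points are arrays, bars are geometric means of 3, and the dotted line is the floor of 16. At 11 d the transected arrays lie above sham for mmp9 (48.4 to 509) and below sham for cyp19a1b (394.5 to 31.6).

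Among 39 measured genes of inflammation and complement, 28 were higher and 8 lower at 11 d, with a median of 0.41. The list rose by camera (adjusted p = 8.3e-12, and adjusted p = 0.0026 with an estimated correlation). Of its members 1 passed over all probe sets and 9 passed adjusted over the list alone: c4, c4b, c6.2, socs3b, irf1b, irf9, isg15, mmp9 and anxa2a. Leukocyte and microglia markers moved with it, at a median of 0.28 with 19 of 23 higher (adjusted p = 1.7e-04, and adjusted p = 0.25 with an estimated correlation, or 0.023 with the replicate block added). The apolipoprotein apoc1 was at 0.75 ± 0.27 (2815 to 4734) and the scavenger receptor marco at 0.92 ± 0.39, and 0 passed over the list alone. Genes of lysosome and autophagy had a median of 0.15 with 24 of 35 higher (0.0013, and adjusted p = 0.29 with an estimated correlation), and the cathepsin ctsla was at 0.79 ± 0.23. Proteasome subunits had a median of 0.10 with 35 of 46 higher (0.0013, and adjusted p = 0.37 with an estimated correlation), and medians of 0.04, 0.38 and -0.08 within pairs 1 to 3. Their largest changes were in parts of the interferon-inducible proteasome, psme2 at 1.24 ± 0.27, psme1 at 0.89 ± 0.33 and psmb10 at 0.65 ± 0.23, and psme2 passed over the list alone. Extracellular matrix genes had a median of 0.08 with 20 of 32 higher (0.013, and adjusted p = 0.11 with an estimated correlation), with mmp9 and the fibrillar collagen col5a2a (0.87 ± 0.23) passing over the list alone. The matrix median was 0.00, 0.15 and 0.15 within pairs 1 to 3. It was as low as 0.0057 over 14 other settings, of which 4 lost the call.

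Axon regeneration genes rose as a list at 11 d, with 34 of 48 higher, a median of 0.20 and a mean of 0.43 (camera adjusted p = 3.9e-09, and adjusted p = 2.6e-04 with an estimated correlation). None passed over all probe sets, and 9 passed adjusted over the list alone: gap43, atf3, junba, tuba1b, tubb5, klf6a, socs3b, cebpd and tmsb. The growth cone protein gap43 went from 1636 to 3961 (1.28 ± 0.28, adjusted p = 0.24 over all probe sets). Further rises were those of atf3, a transcription factor induced in injured neurons, from 71.1 to 280.1 (1.98 ± 0.50, 0.39), its partner junba from 415 to 1586 (1.93 ± 0.43, 0.23) and the tubulin tubb5 from 524 to 1759 (1.75 ± 0.43, 0.35). With the dimmest probe sets left out and the replicate block their adjusted p-values were 0.019, 0.029, 0.042 and 0.027, and jun, at 0.94 ± 0.37, had 0.17. Actin and tubulin genes had a median of 0.07 with 35 of 64 higher (0.0060, and adjusted p = 0.12 with an estimated correlation). Of these tmsb, tuba1b, tuba8l4 and tubb5 passed over the list alone, and tmsb, tuba1b and tubb5 are the genes already given for axon regeneration. All 8 candidates from follow-up studies were higher, with a median of 0.43 (2.2e-04, and adjusted p = 0.0094 with an estimated correlation, or 0.097 with the replicate block added). The vault protein mvp was at 1.00 ± 0.29 and the lysosomal protease lgmn at 0.60 ± 0.18, both passing over the list alone and neither over all probe sets. Of the others, csrp1a was at 0.68, sdcbp2 at 0.52, hmgb1a at 0.34 and l1cama at 0.13. The changes of tncb (0.08, paired SE 0.41) and sox11b (0.08, paired SE 0.15) lay within their spread. The list came from work on this preparation, so its direction is not independent evidence. Markers of neurons were at a median of 0.01 (17 higher, 13 lower, camera adjusted p = 0.39), with the ubiquitin hydrolase uchl1 passing over the list alone.

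Genes of oxidative phosphorylation fell together at 11 d: 84 of 90 were lower, with a median of -0.32 (camera adjusted p = 8.2e-25, and adjusted p = 0.040 with an estimated correlation). With an estimated correlation that pass was lost when the replicate block was added (0.086) and when the dimmest probe sets were left out (0.092). None passed alone. The largest changes were those of cytochrome oxidase subunits cox4i1l (-0.95 ± 0.34) and cox5ab (-0.64 ± 0.16, 1697 to 1088) and of assembly factors ndufaf6 (-0.87 ± 0.34) and ndufaf1 (-0.64 ± 0.22). Outside the list, the mitochondrial gene chchd10 was at -0.66 ± 0.13 and park7, an oxidative stress gene, at -0.72 ± 0.12 (1137 to 690, adjusted p = 0.063). All 13 genes of the cholesterol synthesis list were lower, with a median of -0.90 (3.9e-09, and adjusted p = 0.037 with an estimated correlation, or 0.062 with the replicate block added). Of these hmgcs1 (608 to 288, -1.08 ± 0.33), dhcr7, msmo1 (443 to 169) and fads2, a fatty acid desaturase of the list (2167 to 842, -1.36 ± 0.36), passed over the list alone. Heat shock chaperones were lower in 16 of 22, with a median of -0.23 (0.013, and adjusted p = 0.16 with an estimated correlation), including hsp90aa1.2 at -0.64 ± 0.34. Cytosolic ribosomal proteins were lower in 53 of 74, with a median of -0.07 (0.025, adjusted p = 0.61 with an estimated correlation, and 0.10 with the dimmest probe sets left out). Within pairs 1 to 3 their median was -0.26, 0.02 and 0.01. Without transected replicate 1 it was -0.017 and the list was tested upward.

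Erythrocyte markers fell at 11 d, with 14 of 15 lower and a median of -0.54 (8.8e-09, and adjusted p = 0.0085 with an estimated correlation, or 0.048 with the replicate block added). Over the list alone alas2, the cytoskeletal epb41b, the erythroid transcription factor gata1a (-1.17 ± 0.23, 41.9 to 18.6) and nt5c2l1 (-1.49 ± 0.29, 179 to 63.8) passed. The globins hbaa1 and hbba2 were at -0.26 and -0.84. Endothelial and pericyte markers were lower in 13 of 14, with a median of -0.18 (0.014, and adjusted p = 0.054 with an estimated correlation). The smooth muscle actin acta2 at -0.82 ± 0.17 (846 to 479) passed over the list alone. Radial glia and astrocyte markers did not pass (26 genes, adjusted p = 0.64), with a median of 0.03 and a mean of -0.08, of opposite sign, and an upward test. Of these cyp19a1b passed over the list alone. Glucocorticoid-responsive genes did not pass either (0.26), with a median of -0.02, a mean of 0.16 and an upward test. Over the list alone glula and angptl4 passed. Markers of oligodendrocytes, skeletal muscle and liver and pancreas had medians of -0.03, 0.00 and 0.00 at 11 d and adjusted p-values of 0.96, 0.64 and 0.93. The unfolded protein response was at 0.13 (0.14), glycolysis and hypoxia at -0.09 (0.26), cell cycle at -0.01 (0.29), and apoptosis and p53 at 0.06 (0.36). Trophic factors were at -0.05 (0.81), axon guidance at 0.02 (0.64), neurotransmitter receptors and channels at 0.00 (0.81) and the circadian clock at 0.01 (0.56).

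**Figure D3:**
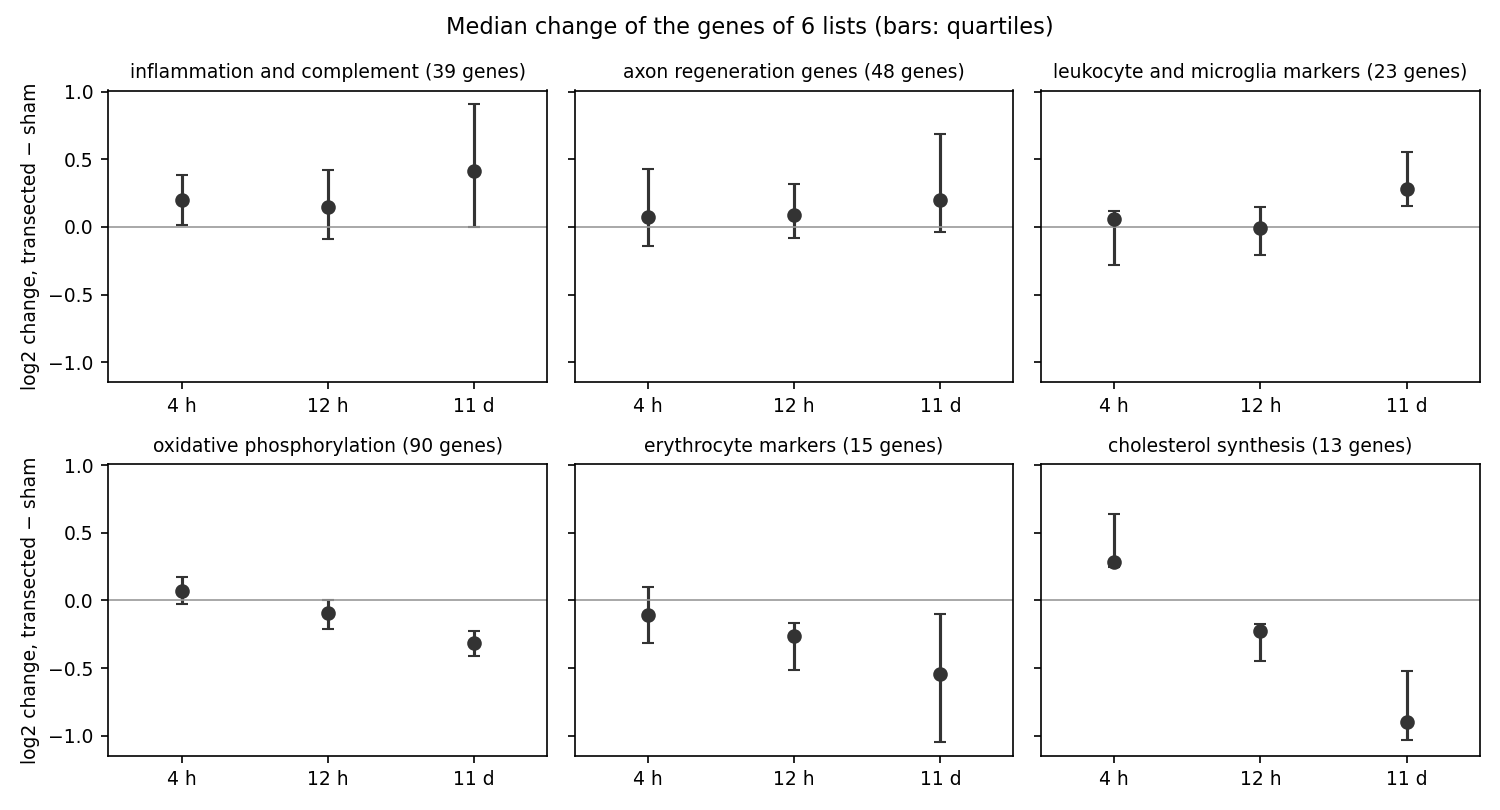
Median log2 change, transected minus sham, of the genes of 6 lists by time after surgery; bars are the lower and upper quartiles over genes. At 11 d the medians are 0.41 for inflammation and complement, -0.32 for oxidative phosphorylation, -0.54 for erythrocyte markers and -0.90 for cholesterol synthesis, which was at 0.29 at 4 h.

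Averaged over the 3 times, 9 arrays against 9, c4b was higher in transected fish at 1.46 ± 0.21 (18.9 to 52.1, limma adjusted p = 0.042), although at 4 h its change was -0.13. The other 5 of the 6 probe sets called, all higher, were Dr.23443.1.A1_at (1.15), Dr.6709.1.S1_at (1.52), Dr.23106.1.A1_at (0.08), cdk5rap2 and cbsb. Each of these 5 rose mainly at a single time, 11 d for Dr.23443.1.A1_at and Dr.6709.1.S1_at and 12 h for the others. All 5 were also called in the test below for effects that differ between times. Their averages therefore do not show a change shared by the 3 times. At an unadjusted p under 0.05 were 621 of the 13493 that vary, where chance gives 674.65. With the dimmest probe sets left out steap4 (1.39 ± 0.24, adjusted p = 0.018) and Dr.18756.1.S1_at (1.57) were also called higher and cyp19a1b lower (-1.54 ± 0.27, 0.018), beside c4b, Dr.23443.1.A1_at and Dr.6709.1.S1_at. With the replicate block alone 0 of the main calls passed (c4b, 0.21). With both settings 11 did, all higher, among them socs3b (1.26 ± 0.27, 0.0034), stat3 (0.97 ± 0.32, 0.0043), atf3 (1.23 ± 0.29, 0.043) and c6.2 (0.99 ± 0.23, 0.018). Of 9 lists called, those of inflammation and complement (median 0.19, adjusted p = 6.6e-11), axon regeneration (0.14, 1.3e-07) and erythrocytes (-0.31, 4.7e-08) also passed with an estimated correlation, at adjusted p = 0.0037, 6.6e-04 and 0.011. With the replicate block added these were 0.0061, 0.0097 and 0.062, so the pass of the erythrocyte list was lost. Oxidative phosphorylation (-0.11), heat shock chaperones (-0.16) and glucocorticoid-responsive genes (0.18) had adjusted p = 0.20 each with an estimated correlation. Cholesterol synthesis (-0.18), the candidates (0.23) and proteasome subunits (0.05) had adjusted p = 0.29, 0.057 and 0.68 with an estimated correlation. The blocked fit added leukocyte and microglia markers (0.018) and ribosomal proteins (0.026), at adjusted p = 0.20 and 0.68 with an estimated correlation.

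The test that the injury effect is equal at the 3 times asked whether early and late responses differ. It called 8 probe sets: tnfaip6, jag1a and the unnamed Dr.23443.1.A1_at and Dr.6709.1.S1_at, which rose at 11 d, and cdk5rap2, cbsb and a further unnamed pair, which rose at 12 h. With the dimmest probe sets left out 2 passed, with the replicate block 1, and 554 had an unadjusted p under 0.05 in the full table. The effect on cholesterol synthesis went from a median of 0.29 at 4 h to -0.90 at 11 d, and all 13 genes had a lower effect at 11 d (median difference -1.39, camera adjusted p = 5.8e-11, and adjusted p = 0.045 with an estimated correlation, or 0.054 with the replicate block added). The effect on axon regeneration genes was higher at 11 d than at 4 h in 31 of 48 (median difference 0.18, 5.6e-04, and adjusted p = 0.019 with an estimated correlation) and than at 12 h in 34 of 48 (0.23, 0.0035, and adjusted p = 0.040 with an estimated correlation). With the replicate block added these estimated-correlation values were 0.0503 and 0.063, so neither passed. Oxidative phosphorylation was lower at 11 d than at 4 h in 82 of 90 (-0.37, 4.4e-19, and adjusted p = 0.083 with an estimated correlation).

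Sham fish alone gave the background of time after surgery, time of day and array handling, which the labels do not separate. The clock gene nr1d2b, a repressor of the circadian loop, rose from 208.5 at 4 h to 509.5 at 12 h (1.29 ± 0.15, limma adjusted p = 0.029). The heat shock factor hsf2 rose from 116 to 293 (1.34 ± 0.19, 0.044), and abracl (-1.03 ± 0.14, 0.042) and the unnamed Dr.1742.1.A1_at (-1.26, 0.044) fell. With the dimmest probe sets left out 0 passed at 12 h against 4 h. In 9 other settings the call was kept by nr1d2b in 4, by hsf2 in 3 and by abracl in 4. Over the list of 30 circadian clock genes alone nr1d2b, bhlhe40 and ciarta (3.28) passed at 12 h against 4 h, while bmal1a, of the opposite arm of the loop, was at -1.50. The list as a whole, with a median of 0.19, did not pass (0.16). Between 11 d and 12 h 3 rose (abracl, the actin crosslinker flna and the alanyl-tRNA synthetase aars1) and 3 fell (hsf2, rims2a and ubtfl). That contrast had 4 calls with the dimmest probe sets left out. Between 11 d and 4 h none passed. The F test over the sham groups called hsf2, nr1d2b, abracl and flna (4 probe sets, 1093 at an unadjusted p under 0.05), 1 with the dimmest probe sets left out and 0 on the deposited scale. GAPDH ratios differed most between these same groups (exact permutation p = 0.1 for 12 h against 4 h, the smallest that 3 against 3 allows).

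Lists in sham fish passed 15 times over the 3 pairs of times, 8 higher and 7 lower, and never with an estimated correlation. Cholesterol synthesis was lower at 12 h than at 4 h, with 11 of 13 genes lower and a median of -0.70 (camera adjusted p = 8.3e-05, and adjusted p = 0.83 with an estimated correlation). Of the other calls, 8 were between 11 d and 4 h, with adjusted p-values of 0.56 to 0.88 with an estimated correlation: immediate early genes (0.26), erythrocyte markers (0.31), the cytoskeleton (0.12) and oxidative phosphorylation (0.10, which was -0.034 with median centring and no longer passed, at 0.10, with the dimmest probe sets left out) higher, and axon guidance (-0.25), glucocorticoid-responsive genes (-0.29), cholesterol synthesis (-0.21) and neurotransmitter receptors and channels (-0.15) lower. Between 11 d and 12 h, 6 passed, with adjusted p = 0.31 to 0.90 with an estimated correlation: erythrocyte markers (0.35), the cytoskeleton (0.22), proteasome subunits (0.24) and oxidative phosphorylation (0.18) higher, and glucocorticoid-responsive genes (-0.33) and neurotransmitter receptors and channels (-0.15) lower. With median centring the split was 3 higher and 10 lower, and on the deposited scale 3 higher and 9 lower.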

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

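The tests of alas2 and nt5c2l1 against the abundant erythrocyte genes were chosen only after the first test of blood content had been seen, and the other tests below were written down before their values were computed.

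The injury effect differed between the 3 times for 8 probe sets (limma F test, adjusted p). Rising at 11 d only were jag1a (0.0187) and tnfaip6 (0.0146). Dr.23443.1.A1_at (1.1e-04) and Dr.6709.1.S1_at (0.0088) rose at 11 d as well. Rising at 12 h were cdk5rap2 (6.1e-05), cbsb (0.0227), Dr.23106.1.A1_at (0.0088) and Dr.17247.1.A1_at (0.0364). Among lists, camera with an estimated correlation gave an effect that differed between 11 d and 4 h for axon regeneration genes (0.0189) and cholesterol synthesis (0.045), and between 11 d and 12 h for axon regeneration genes (0.0405). With the replicate block added these were 0.0503, 0.054 and 0.063, so none passed at 0.05. Of these, jag1a, cdk5rap2, cbsb and Dr.17247.1.A1_at had all sham arrays at the floor at the time they rose, where a spread of zero makes small p-values easy to reach. Among the 115 control probe sets, which were kept out of the tests, limma called 1 at 11 d, AFFX-r2-Bs-dap-3_at, a bacterial spike and not a fish gene, at -0.58. Its unadjusted limma p was 7.6e-06, and 8.7e-04 adjusted over the 115 alone, so the latter is not comparable with the gene calls. It was also the only control probe set at an unadjusted p under 0.05 at 11 d. A p this small can thus arise without a change in the fish.

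Pattern A was the fall of erythroid genes at 11 d, for which less blood in the captured tissue of transected fish was tested. The other 13 erythrocyte genes had a median of -0.37, with quartiles of -0.84 and -0.08 and 12 of 13 lower. This met the bound written down against blood, but by less than its spread, and that bound was wrong to count members near the floor, which can hardly fall: the 11 above the dim range had -0.54 and did not meet it. The abundant hbaa1, hbba2 and cahz were at -0.26, -0.84 and -0.13, with a mean of -0.41. Against that mean alas2 was lower by a further -1.88 ± 0.21. This argues against less blood as its whole cause only if all red-cell transcripts fell alike, which was not tested. The 11 d sham level of alas2 (222) was also above those at 4 h (93.3) and 12 h (79.5). By the same measure nt5c2l1 was at -1.07 ± 0.61, so that for this gene blood and a change of its own could not be told apart. Of the 15 genes, 11 were above the floor on all 9 sham arrays and 0 stood in another list.

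Pattern B was the rise of inflammatory and injury genes at 11 d. More leukocytes in the captured tissue would raise all leukocyte markers, and their median was 0.28 (camera over genes, 1-sided, gave 1.8e-05, but adjusted p = 0.25 with an estimated correlation), between the bounds set beforehand, so cell number and expression could not be told apart. The monocyte and microglia genes cd74a (0.57), apoc1 (0.75) and apoeb (0.55) and the leukocyte gene coro1a (0.33) were higher. The leukocyte gene lcp1 was at -0.03. Too near the floor of 16 to weigh were the neutrophil genes mpx (-0.36, 25.9 to 20.2) and lyz (-0.51, 22.8 to 16). The same held for the leukocyte gene ptprc, which was higher (0.46, 27.4 to 37.6). Of these 23 markers, 19 were above the floor on all sham arrays and 6 stood in another list. With the GAPDH ratio as covariate, the median of the 15 called probe sets' rises was 0.998 of that without it, which met the bound set beforehand against RNA quality. The log2 ratio differed by only 0.15 between the 11 d groups, so the covariate had little difference to adjust for. The test therefore gave no sign of an effect of RNA quality but could not exclude one.

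Pattern C was the fall of cyp19a1b at 11 d. Fewer radial glia in the captured tissue was tested with the other 25 markers of radial glia, astrocytes and ependyma. They had a median of 0.036, with quartiles of -0.19 and 0.28, 14 higher and 11 lower. The list as a whole did not fall with cyp19a1b, which met the bound set beforehand against a loss of radial glia. Higher members included gfap (0.41) and glulb (0.66), and lower ones her4.2 (-0.41) and her9 (-0.29). The list mixes cell types, so a loss limited to the cells that express cyp19a1b was not excluded. Of the 26 markers, 25 were above the floor on all sham arrays and 4 stood in another list. The change of cyp19a1b was -3.50 ± 0.43 under the GAPDH covariate, 0.962 of the -3.64 without it, which met the bound set beforehand against RNA quality. As for pattern B, the ratio differed too little between the 11 d groups for this test to exclude RNA quality.

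Counts were compared with those from other splits of the same arrays. At each time the 6 arrays split in only 10 ways, too few for a share under 0.05. At 4 h the real split called 0 probe sets and the highest other 2 (10 of 10 splits called as many as the real one), or 0 among the 4 splits that part every pair of same-numbered arrays. At 12 h these were 4 and 4 (2 of 10). At 11 d they were 7 and 29 (2 of 10), where the split with 29 put both replicate 3 arrays on one side, and among the 4 splits that part every pair the highest other was 1. For lists they were 8 and 9 at 4 h (2 of 10; 3 among the splits that part every pair), 3 and 6 at 12 h (6 of 10), and 14 and 9 at 11 d (1 of 10; 9 among those). Averaged over times 2 of 100 splits, the real one included, gave the 6 calls or more, with 12 as the highest other. For the effect by time 3 of 100 gave 8 or more, with 13 as the highest other. A random division of the arrays thus gave these counts in a share under 0.05, unadjusted for the number of counts compared. The splits ignored the pairs, and with the replicate block the counts were 0 and 1, so chance was made less likely but not excluded. The share was above 0.05 for lists averaged over times (10 of 100, 9 against 14), for time in sham fish (8 of 100, 4 against 9) and for sham lists (11 of 100, 15 against 17).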

How the results depend on the processing

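Counts of called probe sets depended strongly on settings, while the direction of the named genes and of the lists at 11 d rarely did. For genes named because their groups did not overlap, leaving out an array could not turn the direction. For a gene called in neither setting, a turn was counted only where both changes exceeded their SE. The steady direction of named genes is therefore little evidence that they are robust. With few arrays and signals bounded by background, probe sets at the floor can pass with small changes and dim genes show folds that are too small. At 4 h (0 called) array weights gave 4, a floor at the 20th percentile 2, and leaving out both arrays numbered 3 gave 1. Leaving out an array at 4 h gave 0 to 4: 4 without sham replicate 1, 1 without sham replicate 3, 4 without transected replicate 1 and 1 without transected replicate 3. At 12 h (4 called) the count was 0 without the dimmest probe sets, and stayed 0 with the replicate block or the GAPDH ratio added to that. It was 1 with 1 probe set per gene, 2 with the other floor, 1 with a 2-fold minimum, 2 with the replicate block, though numbers do not pair arrays at 12 h, and 7 on the deposited scale. Leaving out an array at 12 h gave 4 to 27: 8 without sham replicate 1, and 7, 15 and 27 without transected replicates 1, 2 and 3.

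At 11 d (7 called) the count was 15 without the dimmest probe sets, 43 with the replicate block added to that, 14 with the GAPDH ratio added, and 15 with both replicate 3 arrays out as well. It was 12 with 1 probe set per gene, 15 at a threshold of 0.10, 26 without both replicate 3 arrays alone and 1 with only the 6 arrays of that time. Array weights gave 1243, with weights as uneven as 5.43 for sham replicate 1 and 0.29 for both replicate 3 arrays, so that count rests on a few arrays. Leaving out an array at 11 d gave 7 to 21: 19 without sham replicate 3, 12 without transected replicate 2 and 21 without transected replicate 3. Over 10 other settings, each array left out included, c4b was at least 2.59 and called in 7 of 10, cyp19a1b between -3.89 and -3.38 in 7 of 10, alas2 between -2.48 and -1.97 in 4 of 10, and tnfaip6 and jag1a in 9 of 10 each.

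Averaged over times (6 called) array weights gave 73, 1 probe set per gene 1, and the other floor, a 2-fold minimum, the deposited scale, and the GAPDH ratio without the dimmest probe sets 3 each. The replicate block gave 0, and 11 without the dimmest probe sets. Leaving out sham 4 h replicate 1, sham 4 h replicate 2 or sham 12 h replicate 2 gave 3, and leaving out transected 12 h replicate 3 gave 11. For the effect by time (8 called) median centring gave 5, leaving out the dimmest probe sets 2, with the block added 2 and with the GAPDH ratio added 3, array weights 125, 1 probe set per gene 3, the other floor 4, a 2-fold minimum 4, the replicate block 1, and leaving out both 4 h arrays numbered 3 gave 5. Leaving out sham 4 h replicate 2, sham 12 h replicate 2 or sham 11 d replicate 2 gave 5 each, and transected 12 h replicate 3 gave 20. For time in sham fish (4 called) leaving out the dimmest probe sets gave 1 and 0 with the GAPDH ratio added, array weights 2116, the other floor 7, a threshold of 0.10 8, the replicate block 0, the deposited scale 0, and leaving out both 4 h arrays numbered 3 gave 2. Leaving out sham 4 h replicate 1 gave 7, sham 12 h replicate 1 or 2 gave 1 each, and sham 11 d replicates 2 and 3 gave 9 and 15. The cause of these shifts was not tested.

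For lists, an estimated correlation and fry left 0 and 0 of 8 at 4 h, 0 and 0 of 3 at 12 h, 6 and 7 of 14 at 11 d, 3 and 3 of 9 averaged over times, and 0 and 2 of 15 in sham fish. At 4 h the deposited scale gave 5, and leaving out sham replicate 3 gave 2 and transected replicate 1 gave 3, within a range of 2 to 11. At 12 h the mean of all probe sets of a gene gave 1 and the replicate block 5, and leaving out sham replicate 1 gave 1 and transected replicate 3 gave 0, within 0 to 4. At 11 d the range was 10 to 14, averaged 8 to 13, and in sham fish 7 to 16, with 8 without sham 4 h replicate 3 and 7 without sham 11 d replicate 1. The direction of the test turned for 3 list results: neuron markers at 4 h had a median of 0.0079 without transected replicate 1 (and -0.24 without transected replicate 3), the ribosomal proteins at 11 d kept a negative median of -0.017 without transected replicate 1 but were tested upward (-0.14 without transected replicate 3), and oxidative phosphorylation between sham 11 d and 4 h had -0.034 with median centring. At 11 d the replicate block changed no list call at the preset correlation, but with an estimated correlation it ended those of oxidative phosphorylation (0.086), cholesterol synthesis (0.062) and the candidates (0.097) and added leukocyte markers (0.023). The median alone also changed sign, with the test not passing, for proteasome subunits at 11 d without transected replicate 2 (-0.0018) and for ribosomal proteins at 4 h on the deposited scale (-0.016). The lists of axon regeneration (0.16 to 0.24), inflammation and complement (0.26 to 0.47), erythrocytes (-0.74 to -0.19), oxidative phosphorylation (-0.39 to -0.23) and cholesterol synthesis (-1.12 to -0.64) kept their direction at 11 d in all 14 settings. The combined settings, the deposited scale, and leaving out both arrays numbered 3 were added after the data had been seen.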

Other observations

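At 11 d the immediate early genes did not move in a single direction as a list. Of 34 measured, 12 were higher and 19 lower, with a median of -0.11 (camera adjusted p = 0.29), but a test for change in either direction (fry, mixed) gave an adjusted p of 5.3e-05. That test can pass through a few changed members and does not show that the list moved apart. It was run for every list and is given for this list only. Over the list alone the injury-linked transcription factors atf3 (1.98 ± 0.50) and junba (1.93 ± 0.43) rose, and both also stand in the axon regeneration list. The activity-dependent npas4a fell from 91.8 to 24.5 (-1.90 ± 0.53, adjusted p = 0.031), and ccn2a, a target of YAP signalling, from 78.5 to 39.4 (-0.99 ± 0.23, 0.015). Not passing, egr4 was at -1.10, nr4a1 at -1.03, klf2a at -0.97 and dusp1 at -0.88. At 4 h the same list had a median of 0.15, with 23 of 34 higher (0.090). In sham fish the list was higher at 11 d than at 4 h, with a median of 0.26 (camera adjusted p = 0.014, and adjusted p = 0.56 with an estimated correlation).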
